A study of Homo sapiens and synthetic construct with 23 samples.

How the data were processed

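The series measured translation, mRNA levels and eIF4A-bound RNA in a human embryonic kidney cell line with a tetracycline-regulated expression system. The cells had received rocaglamide A (RocA, a plant compound that binds the RNA helicase eIF4A), PP242 (an inhibitor of the mTOR kinase), a compound labelled Hipp, or the solvent DMSO. Hipp was read as hippuristanol, an eIF4A inhibitor, which the labels do not spell out. Ribosome profiling, which sequences the mRNA fragments protected by ribosomes from RNase I, covered 10 libraries. mRNA-seq covered 5 libraries and RIP-seq, sequencing of RNA purified with streptavidin-binding-peptide-tagged eIF4A, covered 4. The series also lists 4 Bind-n-Seq samples, which were not analysed here.

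Per the submitters' processing notes, the tools included CASAVA 1.8, Bowtie2 2.0.6 and TopHat2 2.0.7 with the genome build hg19. The counting program, the annotation release and the counted region are not given in the sources used here. Each of the 19 deposited files held raw read counts for 63691 UCSC transcript identifiers, with no normalization. A second deposited column held a whole number from 5 to 35972 that was identical in all files and resembles a length. Its unit is not stated, and 33.4% of its values were multiples of 3. It was used only to order transcripts, under the name length value.

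The files do not pair the identifiers with gene names, and 0 of them matched the reference gene tables at hand, so results are given for identifiers. Gene lists and named genes fixed before the data were examined could therefore not be applied, nor could scaling to mitochondrially encoded mRNAs or measures of 5′ UTR sequence. No genome coordinates are given for the same reason.

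Neighbouring rows often carried the same or proportional counts, which shows that reads were counted for every transcript that overlaps them. Rows were therefore collapsed before testing. Among the 39620 transcripts with a mean above 20 counts per library, rows within 10 places of each other in the file were joined in either of 2 cases. The standard deviation over the libraries of the log2 ratio of their counts (pseudocount 0.5) was under 0.3, or their counts differed by less than sampling noise (chi-square below its degrees of freedom). The member with the most counts stood for the group. This gave 13778 transcript groups of at most 33 members. Of 29008 random pairs of distant rows, 0.165% met the same criterion. The collapsing and its settings were chosen after the files had been seen and before any test. Limits of 0.2, 0.3 and 0.4 on the standard deviation and windows of 5, 10 and 20 rows were compared by the number of groups, from 12081 to 14851, and by the share of random pairs joined, from 0.0689% to 0.924%. The tests were run with the middle setting only, and overlapping genes or paralogs can still share reads between groups.

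Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr, the quasi-likelihood F test and Benjamini-Hochberg adjustment. A group was called at an adjusted p under 0.05. All 10 ribosome profiling libraries entered 1 fit. RocA and PP242 were compared with DMSO replicates 1 and 2, and Hipp with DMSO replicates 3 and 4, as the design text assigns them. mRNA-seq and RIP-seq were fitted alone. The change in translation efficiency was the interaction term, treated minus DMSO in footprints minus treated minus DMSO in mRNA-seq, over 10 libraries. Dose trends used a score of 0 for DMSO and 1, 2 and 3 for rising doses. Every treated group had 1 library, so the spread came from the DMSO pairs, and the treated library was assumed to vary like them. The residual degrees of freedom were 2 in the footprint fit and 1 in mRNA-seq and in RIP-seq. No label says that DMSO replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Single doses had no replicate check. Log2 fold changes are given with the standard error implied by the F statistic.

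The DMSO pairs differed by more than sampling noise, with a chi-square per degree of freedom of 2.26 and 1.75 in footprints, 1.19 in mRNA-seq and 3.01 in RIP-seq, and each pair was kept as 2 samples. Their counts had a Spearman rho from 0.984 to 0.998. The common coefficient of variation beyond counting noise was 5.92% in footprints, 1.25% in mRNA-seq and 4.74% in RIP-seq. In the translation efficiency fit, which shares 1 spread per group between footprints and mRNA-seq, it was 3.12%.

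Sets of groups were defined from the calls, after these had been seen, as those called with a change of at least 2-fold. In each other comparison the set's median log2 fold change was placed among 10000 random lists matched on mean expression. Lists drawn outside the set and matched on 10 bins of expression and 5 of the length value were added after the results had been seen. Sets were also tested on the dose trends with camera (limma 3.58.1) at a preset correlation of 0.01 and with an estimated correlation. Camera p-values were adjusted over all sets tested on a trend, including sets chosen from that trend's own libraries. Where a treated library held 0 counts, a floor of 3 counts in that library gave a lower bound on the fold, and ratios of 1 to 3 counts carry a 95% exact (Clopper-Pearson) interval. Bounds and intervals cover counting error only. Identifiers were chosen by a rule fixed before the data were examined. It took the called transcripts with the largest change, an average log2 CPM of at least 5 and the same direction against each of the 2 DMSO libraries. No more than 2 that rose and 2 that fell are printed.

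The fits were tested on simulated data with 200 changed groups, drawn from groups with higher counts. For footprints at RocA 3 µM, 22.4% of 1.5-fold, 70.1% of 2-fold and 95.5% of 4-fold changes were recovered, with 3 false calls. For Hipp 1 µM these shares were 7.5%, 44.8% and 84.8%. For RIP-seq at RocA 0.3 µM they were 82.1%, 98.5% and 100%, and for translation efficiency at 3 µM 11.9%, 41.8% and 74.2%. Recovery in groups with few counts was not tested and may be lower. The simulated treated library varied as the fit assumes, and few groups were changed, against 6296 footprint calls at RocA 3 µM. The false calls therefore do not check the assumption made for a single treated library.

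Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter and a filter at a mean of 50 counts. Others were separate fits of the 2 experiments, all 4 DMSO libraries as 1 control, a joint fit of mRNA-seq and RIP-seq, the replicate number as a block, dose in µM, and leaving out single libraries. Every distinct transcript row without collapsing, and footprint counts thinned to the shallowest library, were added after the data had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the remaining steps.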

Results

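The data covered 3 assays in a human embryonic kidney cell line treated with translation inhibitors. Ribosome profiling compared RocA at 0.03, 0.3 and 3 µM and PP242 at 2.5 µM, 1 library each, with DMSO replicates 1 and 2. It also compared Hipp at 0.01 and 1 µM, 1 library each, with DMSO replicates 3 and 4. mRNA-seq covered 2 DMSO libraries and RocA at 0.03, 0.3 and 3 µM, and RIP-seq of tagged eIF4A covered 2 DMSO libraries and RocA at 0.03 and 0.3 µM. Total counts over transcript rows, in which a read can count for several overlapping transcripts, were 10060906 and 7356267 for footprints in DMSO 1 and 2. They were 6222272, 1081474 and 2278962 at the 3 rising RocA doses, 6561354 with PP242, 12827948 and 8402040 in DMSO 3 and 4, and 4547867 and 1055209 at the 2 Hipp doses. mRNA-seq totals lay between 34009149 and 44447889 and RIP-seq totals between 35926209 and 46538650. All changes below are relative to the other transcripts of the same library, so a change in the total amount of translation is not measured.

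The first comparison asked which mRNAs lost or gained ribosomes as the dose of RocA rose. Footprints were redistributed in both directions, and more strongly at the 2 higher doses. At 0.03 µM, 931 of 13271 transcript groups were lower by at least 2-fold and 119 were higher by at least 2-fold. At 0.3 µM these counts were 1800 and 1320, and at 3 µM they were 2576 and 2030. The 0.3 µM library was shallower than that at 3 µM, so the larger counts at 3 µM do not by themselves show a stronger response. In groups with an average log2 CPM of at least 5, the median absolute log2 change was 0.335 at 0.03 µM, 0.803 at 0.3 µM and 0.798 at 3 µM. The lower groups at the lowest dose were mostly lower at the highest dose as well: 649 of the 931 were also among the 2576, and 1 was among the 2030.

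Single transcripts showed the range of the response. Of the transcripts the naming rule selected for translation efficiency at 3 µM, uc003hkm.3 had footprint levels of 94.8 and 83.2 CPM (counts scaled to the library total over groups) in the 2 DMSO libraries, 28.0 at 0.03 µM, 4.48 at 0.3 µM and 0 at 3 µM. With a floor of 3 counts it was at least 24.9-fold lower at 3 µM. At 0.3 µM it held 2 counts, a ratio to DMSO of 0.061 (95% interval 0.0073 to 0.22). Its fall was not particular to RocA, with a log2 footprint change of -0.99 (SE 0.16) with PP242. With Hipp it was -1.95 (SE 0.23) at 0.01 µM and -0.99 (SE 0.32) at 1 µM. The second transcript that fell, uc001rhg.3, went from 54.1 and 50.1 CPM in DMSO to 10.7, 4.48 and 0, at least 14.5-fold lower at 3 µM. At 0.3 µM its 2 counts gave a ratio of 0.10 (0.013 to 0.38). The log2 footprint change of uc001rhg.3 was 0.09 (SE 0.17) with PP242, and 0.13 (SE 0.19) and -0.73 (SE 0.38) at the 2 Hipp doses. In the opposite direction, uc021wxx.1 had 14.6 and 29.1 CPM in DMSO and 46.5, 157 and 384 at the 3 doses, a log2 change of 4.42 (SE 0.20) at 3 µM in the edgeR test, adjusted p = 4.97e-16. The adjacent row uc021wxw.1 rose from 36.3 and 57.2 to 94.6, 291 and 510 CPM, a log2 change of 3.70 (SE 0.16). These 2 rows are next to each other in the files and have low length values, 79 and 184, so they are not independent examples, and reads shared with overlapping transcripts were not excluded.

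**Figure D1:**
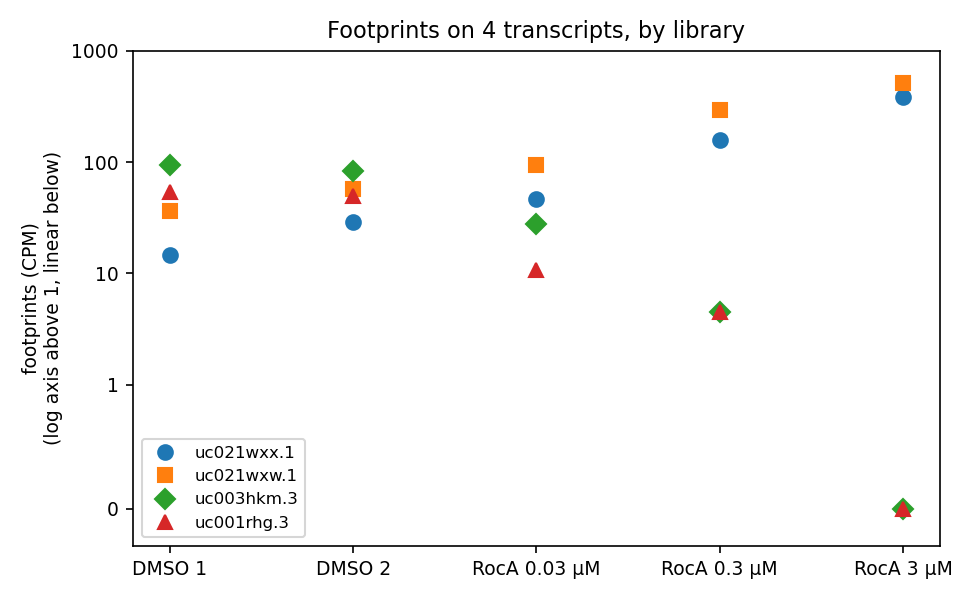
Footprints in CPM (y axis, logarithmic above 1 and linear below) for 4 transcripts in the 2 DMSO libraries and the RocA libraries at 0.03, 0.3 and 3 µM (x axis), 1 point per transcript and library. The 2 transcripts that fell reach 0 counts at 3 µM, and the 2 that rose reach 384 and 510 CPM.

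Counted at any size of change, the edgeR quasi-likelihood test called 3309 groups at 0.03 µM (1475 higher, 1834 lower), 4004 at 0.3 µM (1906 higher, 2098 lower) and 6296 at 3 µM (2998 higher, 3298 lower). Of the groups called lower by at least 2-fold, 24, 332 and 210 held 0 counts in the treated library, and 923, 1600 and 2461 reached 2-fold with those set at the floor. Control libraries also differed from each other. DMSO 1 and 2 against DMSO 3 and 4 gave 3182 calls, 235 higher and 226 lower by at least 2-fold, while the 2 DMSO libraries within a set gave 47 and 5. At 0.03 µM the calls fell to 740 with all 4 DMSO libraries as control, which takes the difference between the sets into the spread. The DESeq2 Wald test called 185 groups at 0.03 µM, and 1618 and 2111 at the higher doses. The balance of directions depended on the method at the higher doses. At 0.3 µM, 1510 groups were higher and 1544 lower by at least 2-fold with DESeq2 size factors, 798 and 541 with the DESeq2 Wald test, and 995 and 903 after thinning to the shallowest library. At 3 µM thinning left 1083 higher and 1058 lower, and at 0.03 µM it left 8 calls, all lower.

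The doses were also compared group by group. Log2 changes at 0.03 and 3 µM had a Spearman rho of 0.64 and a Pearson r of 0.55 across groups, which are not independent replicates. The covariance was 0.683. Unchanged groups simulated against the same DMSO libraries gave a rho of 0.17, an r of 0.15 and a covariance of 0.0613. They gave 0 shared calls, but groups simulated without change are rarely called, so this does not measure what shared controls add to the overlap. Independent lists of the same sizes would share 180.7 lower groups, a baseline that ignores that calls need counts. The DMSO pair leaves 1 library when split, and part of the overlap may come from the shared controls.

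Translation efficiency, footprints relative to mRNA, asked whether the footprint changes went beyond mRNA levels. Changes in translation efficiency were as numerous as those in footprints. The fit shared 1 spread per group between footprints and mRNA-seq, which can understate that of footprints and add calls. At 3 µM, 2479 of 13773 groups were lower in translation efficiency by at least 2-fold and 2248 were higher. At 0.3 µM the counts were 1745 and 1453, and at 0.03 µM 1125 and 285. The 0.3 µM footprint library was shallower than that at 3 µM, so these counts do not by themselves show a rise between those doses. Of the 2479 groups lower at 3 µM, 1350 were also called lower at 0.03 µM and 12 were called higher, where independent lists would share 365.6 lower groups. Independence ignores that calls need counts at both doses. The Spearman rho of the 2 doses was 0.63, and 0.16 in unchanged groups simulated against the same DMSO libraries. For uc021wxx.1 the log2 change in translation efficiency was 1.49 (SE 0.27) at 0.03 µM, 3.66 (SE 0.35) at 0.3 µM and 4.92 (SE 0.21) at 3 µM, and for uc021wxw.1 it was 1.32 (SE 0.18), 3.41 (SE 0.24) and 4.21 (SE 0.16). The lower transcripts uc003hkm.3 and uc001rhg.3 changed by -1.51 (SE 0.18) and -2.70 (SE 0.24) at 0.03 µM.

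The interaction test called 3944 groups at 0.03 µM (1913 higher, 2031 lower), 3878 at 0.3 µM (1896 higher, 1982 lower) and 6074 at 3 µM (3001 higher, 3073 lower). Over the dose score, 6276 groups had a trend in translation efficiency and 5273 in footprints alone. Without DMSO replicate 1 the footprint trend count was 3303, and with dose in µM in place of the score the 2 counts were 1229 and 0. The DESeq2 Wald test called 777, 2480 and 3397 groups in translation efficiency at the 3 doses. At 0.3 µM it found 1265 higher and 886 lower by at least 2-fold, so the excess of lower groups there depended on the method.

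**Figure D2:**
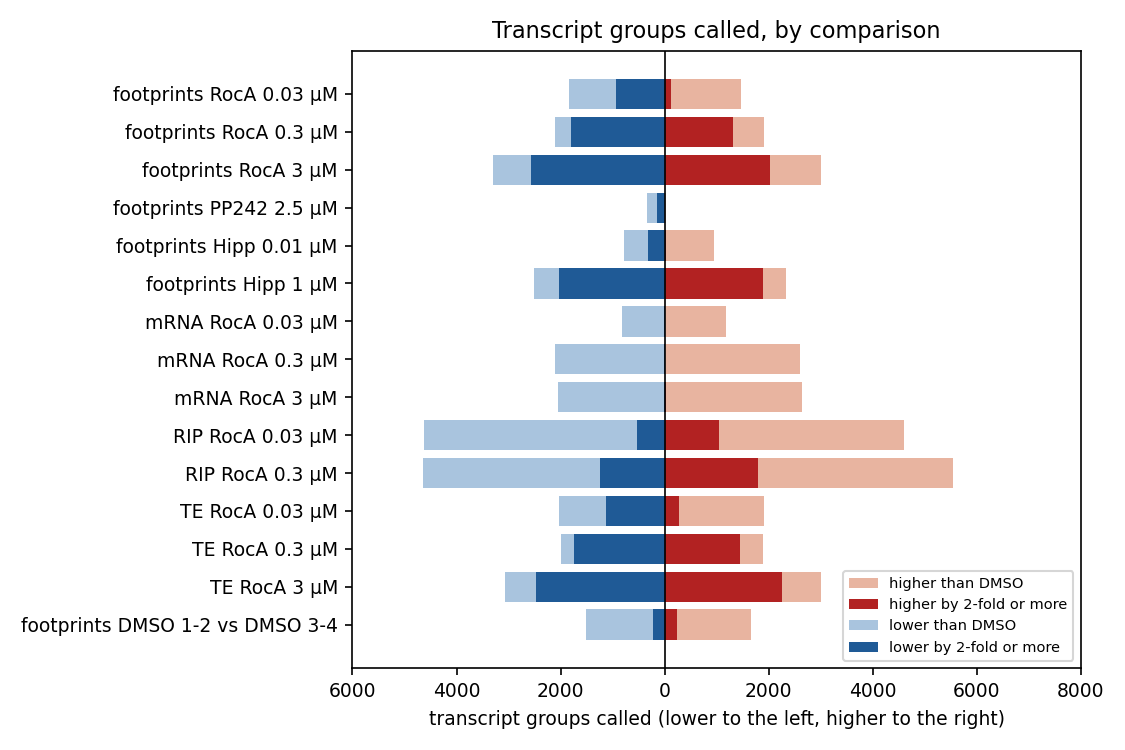
Number of transcript groups called (x axis) in each comparison (y axis), lower than DMSO to the left and higher to the right, with dark bars for changes of at least 2-fold. The bottom bar compares the 2 DMSO sets of ribosome profiling with each other, with 3182 calls, of which 235 and 226 reached 2-fold.

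mRNA levels changed by small amounts. At 3 µM, 2634 groups were called higher and 2056 lower, of 13762, but only 26 and 14 of them changed by at least 2-fold. The counts were 2612 and 2116 at 0.3 µM and 1183 and 823 at 0.03 µM. The transcript uc001rhg.3, whose footprints fell to 0 counts at 3 µM, rose in mRNA by 0.53 (SE 0.05), 0.43 (SE 0.05) and 0.46 (SE 0.05) on the log2 scale at the 3 doses, while uc021wxw.1, whose footprints rose, had mRNA changes of -0.15 (SE 0.04), -0.40 (SE 0.04) and -0.43 (SE 0.04). Across groups, mRNA and footprint changes ran in opposite directions, with a Spearman rho of -0.35 at 0.03 µM, -0.22 at 0.3 µM and -0.20 at 3 µM. Of the 2479 groups with lower translation efficiency at 3 µM, 1030 were called higher in mRNA and 161 lower, but mRNA also enters translation efficiency, so these counts are not independent of how the set was chosen.

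The mRNA calls rest on the small difference between 2 DMSO libraries. Leaving out DMSO replicate 1 or 2 gave 126 and 123 calls at 0.03 µM, 1159 and 1192 at 0.3 µM and 1358 and 1379 at 3 µM in the joint fit with RIP-seq, and 1828 and 1709 trends in place of 3495. The joint fit with all libraries already gave 392, 2823 and 2988 calls, the DESeq2 Wald test 285, 999 and 1052, and dose in µM 0 trends. At 0.03 µM most lower calls were lost, with 347 higher and 45 lower in the joint fit and 125 and 1, or 118 and 5, without a DMSO library.

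RIP-seq asked which RNAs were bound to tagged eIF4A with and without RocA. The bound RNA was redistributed in both directions. At 0.3 µM, 1801 of 13754 groups were higher by at least 2-fold and 1249 lower, and at 0.03 µM 1041 were higher and 537 lower. These changes include changes in mRNA level, and at 0.3 µM the mRNA-seq and RIP-seq changes had a Spearman rho of 0.68. With the mRNA-seq change taken off in a joint fit, 841 groups were higher and 857 lower by at least 2-fold at 0.3 µM. At 0.03 µM these counts were 540 and 485. The joint fit shared 1 spread per group between the assays, which can understate that of RIP-seq. The uncorrected RIP-seq changes at the 2 doses had a Spearman rho of 0.84 across groups, where unchanged groups simulated against the same DMSO libraries gave 0.34. Of the 1801 groups higher at 0.3 µM, 1583 were called higher and 16 lower at 0.03 µM. For uc001rhg.3, RIP-seq rose by 1.14 (SE 0.10) and 0.96 (SE 0.10) on the log2 scale at the 2 doses, while uc021wxw.1 changed by -1.05 (SE 0.09) and -1.70 (SE 0.10). The other lower transcript, uc003hkm.3, differed from that direction, with RIP-seq changes of -0.65 (SE 0.09) and -0.51 (SE 0.09).

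Groups higher with tagged eIF4A were more often lower in translation efficiency. Of the 1801 groups higher in RIP-seq at 0.3 µM, 933 were called lower in translation efficiency at 3 µM and 123 higher. Their median log2 change was -0.86, or -0.83 with groups at 0 counts set at the floor, while 95% of the 10000 matched random lists had medians between -0.22 and -0.08. Of the 1249 groups lower in RIP-seq, 538 were called higher in translation efficiency and 45 lower, with a median of 0.99 and random medians between -0.15 and 0.05. Lists drawn outside each set and matched on the length value as well had medians between -0.19 and -0.07 for the first set and between -0.03 and 0.17 for the second. On the trend in translation efficiency, camera gave an adjusted p of 2.55e-15 for the first set (lower) and 9.21e-14 for the second (higher). With an estimated correlation the adjusted p was 0.0372 and 0.0387, and the unadjusted p 0.0165 and 0.0215. The adjustment included sets chosen from translation efficiency itself, which lowers the adjusted p of the others, so these values are borderline. The 2 assays share no libraries. The first set was also higher in mRNA at 3 µM, with 1134 groups called higher and 11 lower, and the second was lower, with 654 lower and 2 higher. On the mRNA trend camera gave an adjusted p of 8.62e-49 and 5.69e-37 for the 2 sets, and 0.141 for both with an estimated correlation. These mRNA changes enter translation efficiency with the opposite sign. Across all groups at 0.3 µM, RIP-seq and footprint changes had a Spearman rho of -0.16, and a partial rho of 0 given the mRNA-seq change. At 0.03 µM the 2 values were -0.37 and -0.23. In footprints alone at 3 µM the first set had 828 groups lower and 186 higher, with an adjusted p on the footprint trend of 6.16e-08, and 0.0557 with an estimated correlation. The second had 471 higher and 95 lower, with 1.5e-11 and 0.0284.

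In RIP-seq, edgeR called 9232 groups at 0.03 µM (4611 higher, 4621 lower) and 10178 at 0.3 µM (5541 higher, 4637 lower), and the DESeq2 Wald test called 5643 at 0.03 µM. The excess of higher over lower groups at 2-fold depended on the fit. At 0.03 µM it stayed with DESeq2 size factors (1026 higher, 548 lower) and the DESeq2 Wald test (940 and 514) but not in the joint fit with mRNA-seq (822 and 806). At 0.3 µM the size factors gave 1523 and 1509 and the joint fit 1495 and 1520. The RIP-seq trend over dose, 5463 groups, depended on single libraries. It was 1502 without DMSO replicate 1, 1778 without DMSO replicate 2, 10151 without the 0.03 µM library and 9231 without the 0.3 µM library, and 0 with dose in µM.

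PP242 asked what a block of mTOR, the kinase that controls translation of mRNAs starting with a pyrimidine tract, did in the same cells. Its effect was limited to a small set of groups and ran almost entirely 1 way. Of 353 called groups, 334 were lower and 19 higher, and 137 were lower by at least 2-fold, with a median log2 change of -1.60 in those 137. These 137 groups were short, with a median length value of 164 against 408 for all groups. The calls numbered 124 with all 4 DMSO libraries as control, all lower, and 162 with the DESeq2 Wald test, all lower.

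The 137 PP242-lower groups were not lowered as a set by RocA. In footprints at RocA 3 µM, 76 were called higher and 39 lower, with a median of 0.38, inside the range of -0.04 to 0.39 in lists matched on expression and length. Lists matched on expression alone had medians between -0.30 and 0.14. The lists matched on length as well were less abundant than the set in each comparison, with a median log2 CPM of 7.72 against 9.29 in these footprints. The adjusted p on the RocA footprint trend was 0.000635, and 0.394 with an estimated correlation. In translation efficiency at RocA 3 µM, 80 were called higher and 22 lower, with a median of 0.64, against -0.42 to 0.06 in random lists matched on expression. The lowest of 5 bins of groups by length value had a median of 0.60 (interquartile range -0.56 to 1.53). Lists matched on length as well had medians between 0.12 and 0.51, at a median log2 CPM of 7.67 against 9.56 in the set, so part of the shift goes with length and the abundance match is incomplete. The PP242 and RocA footprints share DMSO libraries, which alone would shift such a set downward in both. In RIP-seq at 0.3 µM, 120 of the 133 measured were called lower and 10 higher, with a median of -1.10, against -0.41 to -0.10 in the lists matched on length. In mRNA at 3 µM, 108 of 132 were lower, with a median of -0.25, against -0.16 to -0.11, and this fall enters translation efficiency with the opposite sign. For this set camera gave an adjusted p of 2.4e-08 for the trend in translation efficiency, 9.38e-25 for that in RIP-seq and 5.86e-23 for that in mRNA. With an estimated correlation the adjusted p was 0.134, 0.484 and 0.189.

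Hipp, compared with its own DMSO libraries, asked how another eIF4A inhibitor acts. At 1 µM footprints moved in both directions, with 1895 groups higher and 2039 lower by at least 2-fold. At 0.01 µM 34 groups were higher and 310 lower by at least 2-fold. The balance at 1 µM depended on the scaling, with 2044 higher and 1827 lower with DESeq2 size factors. The 2 Hipp doses had a Spearman rho of 0.14 with each other across groups, and of 0.25 in groups with an average log2 CPM of at least 5. Unchanged groups simulated against the same DMSO libraries gave 0.10 over all groups. Of the 137 PP242-lower groups, 91 were called lower with Hipp at 1 µM and 15 higher, with a median of -1.03, or -0.97 with the group at 0 counts at the floor, and random medians between -0.79 and -0.36. Lists matched on length as well had medians between -0.97 and -0.50, so the value at the floor lay at their edge. The set's camera adjusted p on the Hipp trend was 1.94e-09, and 0.481 with an estimated correlation.

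In all, edgeR called 1730 groups at 0.01 µM (951 higher, 779 lower) and 4860 at 1 µM (2341 higher, 2519 lower). At 0.01 µM the call count was 2481 in a fit of the Hipp set alone and 1 with all 4 DMSO libraries as control. The DESeq2 Wald test called 86 groups at 0.01 µM and 1714 at 1 µM. The edgeR test found 0 groups with a Hipp trend, 2898 at an unadjusted p under 0.05, and DESeq2 found 804. Without DMSO replicate 3 or 4 the trend count was 189 and 211, without the 0.01 µM library 5041 and without the 1 µM library 2372.

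RocA at 3 µM and Hipp at 1 µM differ in dose, so their values stand side by side. The 2 compounds changed partly overlapping groups. Both lowered 673 groups by at least 2-fold, where independent lists would share 395.8, and both raised 489, where independent lists would share 289.9. Independence may be too low a baseline for the lower groups, because lower calls gather in groups with more counts. At least 2015 of 2519 Hipp-lower calls and 2072 of 3298 RocA-lower calls had an average log2 CPM of at least 5. Of all 13271 groups, 5424 did. RocA lowered and Hipp raised 149, against 367.8 for independent lists. The Spearman rho across groups was 0.22 and the Pearson r 0.19, with no shared libraries. Of the 2039 groups lower with Hipp, 894 were called lower and 433 higher with RocA at 3 µM, with a median of -0.48, or -0.47 at the floor, below the random range of -0.22 to -0.11. On the RocA footprint trend, camera gave that set an adjusted p of 0.000344, and the adjusted p was 0.0615 with an estimated correlation. Of the 1895 groups higher with Hipp, 642 were called higher and 194 lower with RocA, with a median of 0.49 and an adjusted p of 3.8e-06, or 0.0298 with an estimated correlation. A direct test of the difference between the 2 changes called 4429 groups, but 1525 with the DESeq2 Wald test and 1898 after thinning to the shallowest library. For uc021wxx.1 the difference was 5.54 (SE 0.58) on the log2 scale, and for uc021wxw.1 it was 3.15 (SE 0.32).

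Changes with RocA at 3 µM and PP242 showed no positive relation across groups, with a Spearman rho of -0.02, a Pearson r of 0.01 and a covariance of 0.00422. Unchanged groups simulated against the same DMSO libraries gave a rho of 0.18, an r of 0.15 and a covariance of 0.0558, above the observed values. With different DMSO replicates the rho was -0.11 and -0.03, and in groups with an average log2 CPM of at least 5 it was -0.20, a weak tendency in opposite directions. Both lowered 11 groups by at least 2-fold, where independent lists would share 26.6.

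**Figure D3:**
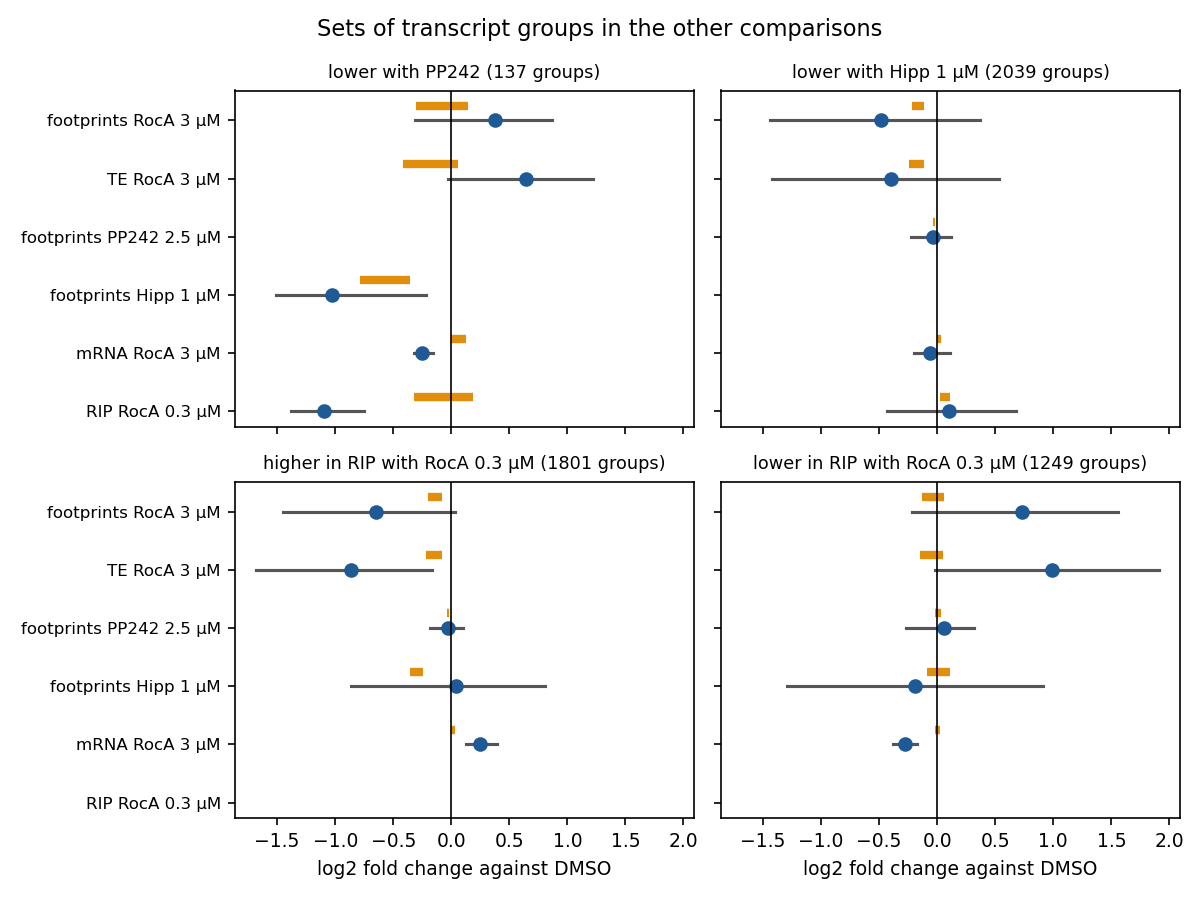
Median log2 fold change against DMSO (x axis, points) with the interquartile range (grey lines) of 4 sets of transcript groups in the comparisons that did not define them (y axis), and the 95% range of medians of 10000 random lists matched on mean expression (orange bars). The PP242-lower set lies at 0.64 in translation efficiency with RocA 3 µM and at -1.10 in RIP-seq.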

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

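The tests of the mRNA change as a common cause at RocA 0.3 µM over all groups, and of the PP242 calls against all 4 DMSO libraries, were chosen after their results had been seen.

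The change in RIP-seq differed from the change in mRNA-seq at the same dose in 7028 groups at RocA 0.03 µM (3125 higher, 3903 lower) and in 7894 groups at 0.3 µM (4054 higher, 3840 lower), by a test of the difference in 1 fit of both assays. That fit shared 1 spread per group between the assays, which can understate that of RIP-seq and add calls. RIP-seq calls rose in it from 9232 to 9670 at 0.03 µM and from 10178 to 10465 at 0.3 µM. The difference was not tested with DESeq2. The footprint change at RocA 3 µM differed from that at Hipp 1 µM in 4429 groups, by a test of the difference between compounds, which were given at different doses in different experiments. The DESeq2 Wald test called 1525 groups for this difference.

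Groups that rose in RIP-seq at RocA 0.3 µM tended to fall in translation efficiency at the same dose, with a Spearman rho of -0.21 across 13749 groups. A linear adjustment on ranks for the length value and the mean count left a partial rho of -0.18, so it did not remove the relation. The length value has no stated unit, so this adjustment cannot exclude transcript length and abundance. At 0.3 µM the mRNA-seq change went with RIP-seq (rho 0.68) and against footprints (rho -0.22), and it enters translation efficiency with the opposite sign. RIP-seq against footprints had a rho of -0.16 and a partial rho of 0 given the mRNA-seq change. In well-covered groups the partial rho was 0.07. A change in mRNA level common to both assays would move them together, so it would not by itself give a negative rho. At 0.3 µM no negative relation of RIP-seq with footprints was left given the mRNA-seq change. Why the mRNA-seq change ran against footprints was not tested, so the partial rho cannot decide whether mRNA level is a cause. At 0.03 µM the same correction left a partial rho of -0.23, from -0.37, so a negative relation remained after it. A direct effect of eIF4A held on these mRNAs by RocA, the biological explanation the design names, stays open and was not tested.

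Changes in mRNA-seq and footprints ran in opposite directions at RocA 3 µM, with a Spearman rho of -0.20 across 13255 groups. Length and abundance could account for part of it, since the partial rho given both was -0.12. The same adjustment cannot exclude that they account for more. Whether mRNAs that lose ribosomes are kept longer in the cell, or another process changes both, was not tested.

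Footprint changes with the weaker treatments were set against differences between experiments, which 1 DMSO library against the DMSO pair of the other set measures. Each treatment was compared with the DMSO pair of its own set, so a difference between the sets does not enter its change. The DMSO values therefore give only a scale. The DMSO libraries were also deeper than the treated ones, so counting noise adds less to their values. All 4 DMSO libraries as 1 control take that difference into the spread, so a fall in calls there was partly built in. In groups with an average log2 CPM of at least 5, the median absolute log2 change at RocA 0.03 µM was 1.32 times the highest of the 4 DMSO values. With all 4 DMSO libraries as control 740 calls were made. At Hipp 0.01 µM the ratio was 1.11 and 1 call was made with that control, while a fit of the Hipp set alone made 2481. With 1 treated library, these values cannot settle whether the treatment caused the changes. With PP242 the ratio over all such groups, called or not, was 0.539, smaller than the difference between the sets. Of the 353 calls, 124 were also made with all 4 DMSO libraries and these stand apart from that difference. An effect of each compound stays among the open explanations.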

How the results depend on the processing

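Leaving the rows uncollapsed, thinning the footprint counts, matching the random lists on length and the settings of the collapsing were chosen after the data had been seen. Of the alternatives for counts of calls, 75 gave fewer calls and 66 as many or more within 1.5 times the main count, and outside that range 44 gave fewer and 28 more. The 4 named transcripts kept their direction and their adjusted p under 0.05 in translation efficiency at RocA 3 µM under all 10 alternatives run for each. At the preset correlation all 45 set tests kept their side of the threshold with DESeq2 size factors. Some of them tested a set on libraries that had chosen it, so their side was largely fixed in advance. At the estimated correlation 43 of the 45 kept their side. The Hipp-lower set on the trend in translation efficiency went from a camera adjusted p of 0.048 to 0.212. The RIP-higher set on the RocA footprint trend went from 0.0557 to 0.0459. Scaling to mitochondrial mRNAs, the 5′ UTR measures, the fixed gene lists and the alternatives for normalized values were not run, because the files hold counts on identifiers without names or sequence. Depth is 1 limit of the footprint results, with totals of 1055209 counts at Hipp 1 µM and 1081474 at RocA 0.3 µM, and the single library per treatment is another.

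The values outside 1.5 times follow by setting, and their cause was not tested unless stated. The DESeq2 Wald test called 185, 1618 and 2111 groups in footprints at the 3 RocA doses, 162 with PP242, 86 and 1714 with Hipp, and 1525 for RocA 3 µM minus Hipp 1 µM. It called 285, 999 and 1052 in mRNA-seq, 5643 in RIP-seq at 0.03 µM, 777, 2480 and 3397 in translation efficiency, and 2211 mRNA and 804 Hipp trends. Every distinct transcript row, which repeats shared reads, gave 8326, 9386 and 14874 footprint calls with RocA, 821 with PP242, 4226 and 12012 with Hipp, and 10068 for the difference. It gave 4911, 11303 and 11142 in mRNA-seq, 23349 and 26175 in RIP-seq, 9681, 9027 and 14523 in translation efficiency, and trends of 12472 in footprints, 7744 in mRNA, 12909 in RIP-seq and 14841 in translation efficiency. All 4 DMSO libraries as control gave 740 at RocA 0.03 µM, 124 with PP242 and 1 at Hipp 0.01 µM. Thinning, which leaves fewer counts, gave 8, 2296 and 2529 with RocA, 111 with PP242, 0 and 3025 with Hipp and 1898 for the difference. mRNA-seq fitted jointly with RIP-seq gave 392, 2823 and 2988. Dose in µM gave 0 trends in RocA footprints, mRNA-seq and RIP-seq, 1229 in translation efficiency and 3385 with Hipp. A mean of 50 counts gave 3440 RocA footprint trends, and no filter gave 1687 Hipp trends, where edgeR called 0 with the filter and 2898 at an unadjusted p under 0.05.

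Leaving out 1 DMSO library of mRNA-seq leaves no replicate there, so it was done in the joint fit with RIP-seq. It gave 123 to 126, 1159 to 1192 and 1358 to 1379 mRNA calls at the 3 doses, from 392, 2823 and 2988 in that fit. The trends ranged from 3303 to 5068 in RocA footprints, 1709 to 4092 in mRNA-seq, 1502 to 10151 in RIP-seq and 189 to 5041 with Hipp. With 1 DMSO library left, it was assumed to vary like the other groups. Among groups with an average log2 CPM of at least 5, the Spearman rho of RocA 3 µM with PP242 was -0.20 and with Hipp 0.16, that of RIP-seq with footprints -0.26 and with translation efficiency -0.32 at 0.3 µM, and that of mRNA-seq with footprints at 3 µM -0.29. With different DMSO replicates, RocA with PP242 had -0.11 and mRNA-seq with footprints -0.18. The replicate block, with libraries of the same number paired across assays, gave 3872, 4385 and 6292 calls in translation efficiency. Deviations of same-numbered DMSO libraries correlated by 0.01 between footprints and mRNA-seq. The mRNA-seq pair differed by little more than sampling noise (chi-square per degree of freedom 1.19), so this cannot decide whether the numbers mark pairs.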

Other observations

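The counts of the eIF4A purification were less concentrated in the top groups with RocA. In each library the 100 groups with the most counts in that library were summed. They held 30.37% and 29.82% of the counts in the 2 DMSO RIP-seq libraries, 21.26% at RocA 0.03 µM and 18.84% at 0.3 µM. In the mRNA-seq libraries each library's own top 100 held between 20.1% and 21.65%. Of the 100 groups most abundant in DMSO RIP-seq, 90 were called lower in RIP-seq at 0.3 µM and 6 higher, with a median log2 change of -1.13, and 84 were called lower in mRNA-seq at 0.3 µM, with a median of -0.24. They were chosen on the DMSO libraries that form the denominator in RIP-seq, which favours a fall. For this set camera gave an adjusted p of 4.95e-22 on the RIP-seq trend, and 0.484 with an estimated correlation. The 2 values were 5.71e-21 and 0.189 on the mRNA trend, and 0.0162 and 0.43 on the RocA footprint trend. Of the same 100 groups, 85 were called lower with PP242, with a median of -1.54. In footprints at RocA 3 µM 58 of them were called higher and 28 lower. The percentages above are shares of a library, so a loss in these groups raises the shares of others. The log2 changes used TMM scaling, and their median over all groups was 0.08 in RIP-seq at 0.3 µM.

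RocA and Hipp changes also sorted by the length value in opposite directions. At RocA 3 µM the median log2 footprint change was 0.40 in the lowest of 5 near-equal bins of groups by length value and -0.44 in the highest. At Hipp 1 µM the medians were -0.50 and 0.25, and with PP242 0.01 and 0.01. In mRNA-seq at RocA 3 µM they were -0.17 and 0.18, and in RIP-seq at 0.3 µM -0.32 and 0.41. For footprints at RocA 3 µM the spread within a bin was wider than the difference between bins, with an interquartile range of -0.64 to 1.30 in the lowest bin. In mRNA-seq it was narrower, -0.30 to 0 in the lowest bin and 0.03 to 0.32 in the highest.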
